A study of Mus musculus with 7 samples.

How the data were processed

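Total RNA of mammary glands of PyV-MT mice on control chow (3 arrays) or CLA chow (4 arrays) was biotin-labelled and hybridised to 1-colour Affymetrix arrays of 45101 probe sets, per the labels' protocols. The deposited values were MAS5 signal intensities on a linear scale, per the submitters' processing notes. The MAS5 version, the genome build and the annotation are not given in the sources used here. Each array's mean signal with 2% trimmed at each end was 500.003, so the deposited intensity values were already scaled between arrays and were used as they were. This scaling assumes that total signal is equal between glands, so every change is relative to the rest of the transcripts in a gland. The array comes from bulk tissue, and the lists of cell type markers are read as transcript levels, not cell numbers.

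Groups came from the diet named in the labels. Each array is taken as a separate animal because the labels describe each sample as a mouse. Of the mice that the study placed on the diets, 5 and 6, the arrays here cover 3 and 4. The titles carry experiment numbers, and their leading digits, 27 or 28, were treated as a possible batch. The meaning of these numbers is not given in the sources used here.

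Signals below 1 were set to 1 and log2 was taken without a pseudocount. The 64 Affymetrix control probe sets were left out of the tests. Of the others, 34945 had 1 gene symbol, 932 had several and 9160 had none, and only those with 1 were used. For 34741 of them the symbol was looked up by its Entrez gene identifier in a RefSeq gene table of assembly GRCm38.p6, used for names alone. A gene with several probe sets was represented by that with the highest mean log2 signal over all arrays. This gave 18193 genes, of which 12497 with a mean at or above the 40th percentile of probe sets, a signal of 57.7, were tested and 5696 were not. Low MAS5 signals carry background, so changes of dim genes are uncertain in size.

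The comparison, CLA minus control, was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend, 4.53 prior degrees of freedom), two-sided, without covariates, and p-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Intervals are at 95%. Limma's camera tested 20 of 22 gene lists, those with at least 5 members tested, with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with a correlation estimated per list, and the rotation test fry, were run beside it. A list score is the mean over members of log2 signal minus the gene's mean over the 7 arrays. Scores were compared by a two-sided exact permutation test over all 35 splits. The smaller one-sided share was doubled, so the smallest p this test can give is 0.0571. Over the 22 lists the smallest adjusted exact p was 0.419, so no list score passed after adjustment. Members were also counted as risen or fallen when adjusted over the list alone.

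The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Named genes were the 12 largest changes in each direction among genes past the threshold with separate groups. Where fewer than 5 passed, they were the 10 of smallest p with separate groups in that direction and no clone or predicted-gene name. Fasn was always named, as were the 4 members of smallest p of each list. Fads2 and Srebf1, outside this rule, were chosen after their values were seen, as were Myh4, Ucp1 and Acta1.

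On simulated data with these genes, group sizes and spreads (20 simulated comparisons of 12497 genes, 200 of them changed), the limma fit recovered 54.15% of genes changed 2-fold and 93.4% of genes changed 4-fold, with 9.2 false calls on average. The simulated noise was independent between genes, without variation shared on an array, so these shares need not hold for the real arrays. There 0 genes passed over all genes, although Retn was 4.11-fold lower. Of 200 simulated lists of 20 genes without an effect and with a correlation of 0.5, camera with the preset correlation called 53.5%, camera with an estimated one 3% and fry 5%.

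Alternatives were quantile normalization, median centring and cyclic loess, pseudocounts of 16 and 64, the mean of a gene's probe sets, no filter and a 60th percentile filter, robust and untrended eBayes, array weights, all probe sets, a per-gene unequal-variance test, a threshold of 0.1, the title number as a block, the arrays with title numbers starting with 28 alone, and each array left out in turn. The muscle score and the 3′ to 5′ ratio as covariates were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.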

Results

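Mammary glands of virgin female mice that carry the polyoma virus middle T oncogene (PyV-MT), which drives mammary tumours, were profiled at 8 weeks of age on Affymetrix arrays. The mice had eaten for 4 weeks either control chow or chow with 1% conjugated linoleic acid (CLA), a mixture of linoleic acid isomers whose double bonds are conjugated. The study placed 5 mice on control chow and 6 on CLA chow, and 3 control and 4 CLA glands are compared here, each on its own array. The values were MAS5 signal intensities, with a trimmed mean of 500.003 on each of the 7 arrays. Pearson correlation between arrays, taken across genes, lay between 0.919 and 0.972, and the highest value joined control replicate 1 with CLA replicate 1. These are the 2 arrays whose title numbers start with 27. The other 2 control and 3 CLA arrays have title numbers that start with 28. The 3′ to 5′ signal ratio of the Actb control probe sets, a measure of RNA integrity, was 2.78 on CLA replicate 3 and between 1.41 and 1.88 on the other arrays. The small number of arrays limits the precision of every value below.

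The series title names fatty acid synthase as the gene suppressed by CLA, so its transcript Fasn was examined first. Fasn signal was 15524 ± 2795 (SD, n = 3) in control glands and 6631 ± 1309 (SD, n = 4) in CLA glands, 2.34-fold lower. All 4 CLA arrays, from 5761 to 8576, lay below all 3 control arrays, from 12341 to 17578. The log2 change of Fasn was -1.23 ± 0.18 (SE), with a 95% interval from -1.63 to -0.83 and limma's unadjusted p of 5.06e-05, the smallest of the 12497 genes tested. Its limma adjusted p was 0.294 over all genes and 0.00127 when adjusted over the list alone, the list being that of fat synthesis. Within the arrays with title numbers starting with 27 the Fasn difference was -1.47 on the log2 scale, from 1 array per group, within those starting with 28 it was -1.13, and with this number as a block it was -1.23. Without CLA replicate 4 the change was -1.36 and the limma adjusted p over all genes was 0.0227.

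Across all genes, limma called 0 higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.294. At an unadjusted p under 0.05 there were 298 genes with higher and 376 with lower signal, in all 674 or 5.39% of those tested. A per-gene unequal-variance test called 0 genes after adjustment and 485 at an unadjusted p under 0.05. The groups did not overlap for 664 genes, 5.31%, where chance gives 5.71%. Leaving out CLA replicate 4 gave 17 lower genes, and leaving out control replicate 1 gave 2 higher genes. The number at an unadjusted p under 0.05 was 1377 without control replicate 1, 370 without control replicate 2 and 438 without CLA replicate 2.

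Among the 10 genes of smallest p with lower signal and separate groups, none past the threshold over all genes, were 6 that belonged to the lists of fat synthesis, white adipocyte markers or fatty acid oxidation fixed beforehand, namely Fasn, Acaca, Retn, Cd36, Ucp3 and Acadl. Acaca, acetyl-CoA carboxylase, which makes the malonyl-CoA used by Fasn, had a log2 change of -1.23 ± 0.21 (SE), and Retn, which encodes the adipocyte hormone resistin, -2.04 ± 0.33. The other 4 were Hsd11b1, which regenerates active glucocorticoid, at -1.33 ± 0.20, Abcd2, a peroxisomal fatty acyl transporter, at -2.11 ± 0.33, Pygl, a glycogen phosphorylase, at -2.16 ± 0.36, and Tmem182 at -1.77 ± 0.30. The 10 genes with higher signal, also none past the threshold, included the basal keratins Krt17 at 1.67 ± 0.39 and Krt5 at 1.24 ± 0.31, Ddah1 at 0.94 ± 0.15 and Rcor2 at 1.60 ± 0.34. They also included the tight junction gene Cldn23 at 1.10 ± 0.24, Epha3 at 1.39 ± 0.33, Ptprv at 0.88 ± 0.18, Uhrf1, which maintains DNA methylation during replication, at 0.86 ± 0.20, and the valyl-tRNA synthetase gene Vars at 0.68 ± 0.17. Timp2, an inhibitor of matrix metalloproteinases, had 0.46 ± 0.11 on its brightest probe set and -0.22 as the mean of its probe sets. Limma's adjusted p over all genes ran from 0.294 to 0.688 for these 20 genes. Control signals of Krt17 (43.3 to 132), Rcor2 (28.5 to 64.6) and Epha3 (56.4 to 67.7) lay partly below the filter signal of 57.7. So did the CLA signals of Abcd2 (42.9 to 78.4) and Tmem182 (56.4 to 111). Between control replicate 1 and CLA replicate 1, Krt17 was 132 against 180 and Krt5 1476 against 1731. Under alternatives other than a left-out array, log2 changes ran from 0.85 to 1.69 for Rcor2 and 1.01 to 2.25 for Krt17. Those of Krt5 ran from 0.75 to 1.73, Uhrf1 from 0.44 to 1.16 and Epha3 from 0.86 to 1.90. Among the lower genes, Acaca ran from -1.59 to -0.84, Abcd2 from -2.31 to -1.38, Tmem182 from -1.89 to -1.22 and Ucp3 from -2.57 to -1.52.

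**Figure D1:**
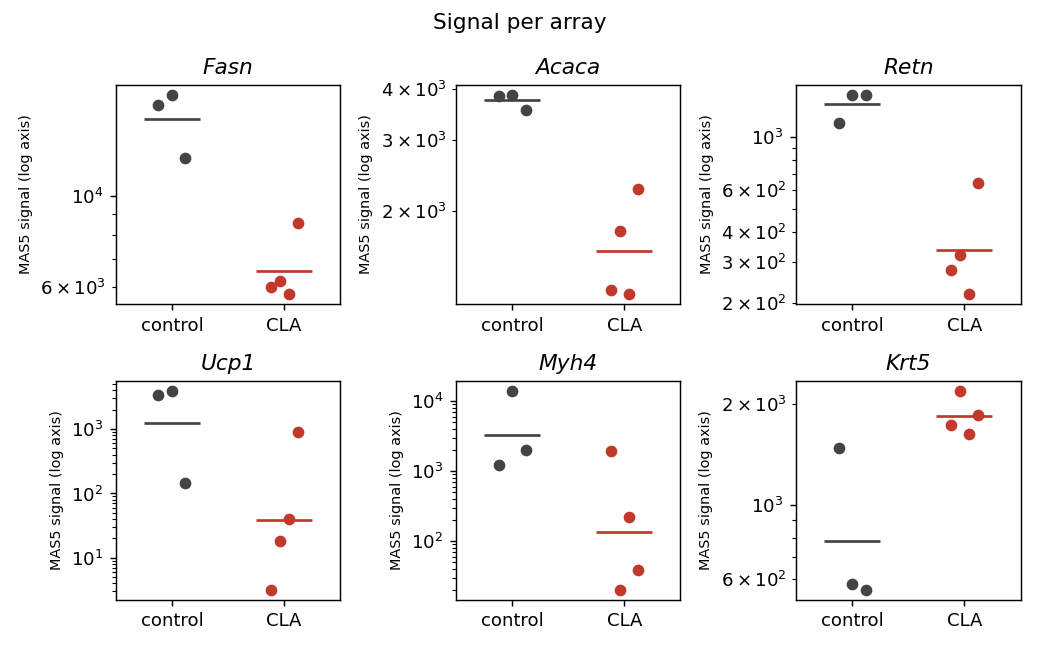
MAS5 signal on a log axis of 6 genes on each control array (grey points, n = 3) and each CLA array (red points, n = 4), with lines at the geometric means. Fasn lies between 5761 and 8576 on the CLA arrays and between 12341 and 17578 on the control arrays, while Myh4, of skeletal muscle, spans a wide range within both groups.

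The fat synthesis list was lower in CLA glands. Of its 25 members, all tested, 17 fell and 1 rose when adjusted over the list alone, and 0 passed over all genes. Dgat2, which forms triglyceride, fell 3.77-fold (log2 change -1.91 ± 0.37 SE), Acss2, which makes acetyl-CoA from acetate, fell 2.37-fold, and Fasn and Acaca fell 2.34-fold and 2.35-fold. The exception was Fads2, a fatty acid desaturase, which rose by 0.57 ± 0.16 on the log2 scale, with a limma p of 0.0132 adjusted over the list alone. Srebf1, a transcriptional activator of the pathway, had 0.01 ± 0.18 and did not pass. The mean log2 change of the list was -0.62 (camera adjusted p = 7.47e-16 with the preset correlation). The adjusted p = 0.165 with an estimated correlation, and the exact permutation p of the list score was 0.0571, the smallest that this test can give. Because the title drew fatty acid synthase from these samples, this list is not independent evidence of its direction. The mean was -0.70 within title numbers starting with 27, -0.61 within those starting with 28 and -0.64 with the number as a block. Only 7 members fell without control replicate 2 and 10 without CLA replicate 2.

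White adipocyte markers were lower by a larger amount. Of 20 tested members, 20 had a negative change and 18 fell when adjusted over the list alone, with 0 passing over all genes. Retn fell 4.11-fold, Cd36, a fatty acid importer, 2.83-fold, Lpl, lipoprotein lipase, 2.00-fold, and Fabp4, the adipocyte fatty acid binding protein, 2.46-fold. The list's mean log2 change was -1.29 (camera adjusted p = 6.05e-29; adjusted p = 0.126 with an estimated correlation), and the exact permutation p of its score was 0.0571. Within title numbers starting with 27 the mean was -1.54, within those starting with 28 it was -1.21, and with the block it was -1.31. On CLA replicate 4 the score was 0.30, against -0.96 to -0.75 on the other CLA arrays and control values of mean 0.74 ± 0.12 (SD, n = 3). The synthesis score minus the adipocyte score was -0.38 ± 0.07 (SD, n = 3) in control and 0.29 ± 0.31 (SD, n = 4) in CLA glands. Averaged over members, the synthesis list was thus lower by less than the adipocyte list. This difference of 0.67 had an exact permutation p of 0.0571, the smallest that this test can give. It was 0.84 and 0.60 within title numbers starting with 27 and 28 and 0.67 with the block. The difference holds for the list means and not for each gene. Of the 25 synthesis members 6 had a positive change, while Fasn, Acaca, Acss2 and Dgat2 had -1.23, -1.23, -1.24 and -1.91.

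**Figure D2:**
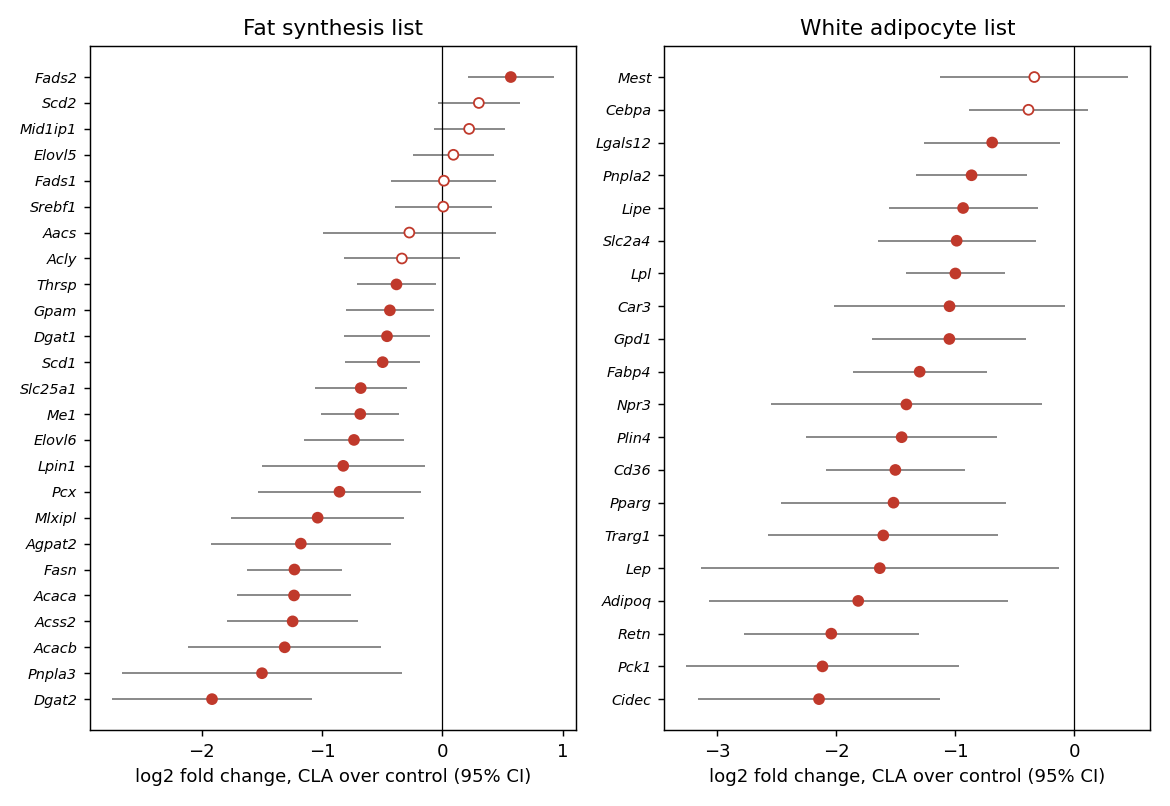
Log2 fold change, CLA over control, of each tested member of the fat synthesis list (left, 25 genes) and the white adipocyte list (right, 20 genes), with 95% confidence intervals from limma (3 control and 4 CLA arrays). Filled points passed when adjusted over the list alone, 18 on each side, and Fads2 is the only filled point above 0.

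Fatty acid oxidation genes were lower as well. Of 23 tested members 16 fell when adjusted over the list alone, 0 rose, and 0 passed over all genes. Ucp3, a mitochondrial carrier of muscle and brown fat, fell 3.92-fold, Pdk4, which restrains glucose oxidation, 7.87-fold, and the acyl-CoA dehydrogenases Acadl and Acadm 1.67-fold and 1.57-fold. The list's mean log2 change was -0.62 (camera adjusted p = 1.45e-22; adjusted p = 0.0872 with an estimated correlation). It was the only list past the rotation test fry, with an adjusted p of 0.0402. The exact permutation p of the score was 0.0571, and the mean was -0.82 and -0.54 within title numbers starting with 27 and 28 and -0.62 with the block. The number that fell was 10 without control replicate 1, 4 without control replicate 2 and 7 without CLA replicate 1. Oxidative phosphorylation genes, by contrast, had a mean of only -0.07, with 0 of 33 members past the test over the list alone or over all genes. Its camera adjusted p = 0.0103 became adjusted p = 0.564 with an estimated correlation, and the call ended without control replicate 1 or CLA replicate 3 (means -0.05 and -0.03), as means of a gene's probe sets (camera adjusted p = 0.0868), with the 3′ to 5′ ratio as a covariate (camera adjusted p = 0.0787) and within title numbers starting with 28 (camera adjusted p = 0.255), while the mean was -0.11 without control replicate 3 and -0.13 without CLA replicate 4. With the muscle score as a covariate it was -0.13 (camera adjusted p = 0.000822). Its members of smallest p, Ndufa1 (-0.26), Cycs (-0.27), Sdhc (-0.20) and Ndufb9 (-0.16), did not pass, and Cycs and Ndufb9 had the other sign as means of their probe sets, at 0.14 and 0.27.

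Brown adipocyte markers varied between arrays of each group. Of 10 tested members 6 fell when adjusted over the list alone and 0 over all genes, including the lipid droplet gene Cidea (9.82-fold), the cytochrome oxidase subunits Cox7a1 (2.87-fold) and Cox8b (5.82-fold), and the proton channel gene Otop1 (1.95-fold). With an array left out the log2 change of Cidea ran from -4.12 to -2.80 and that of Cox8b from -3.14 to -1.96. The mean log2 change was -1.71 (camera adjusted p = 3.09e-08; adjusted p = 0.165 with an estimated correlation), with an exact permutation p of 0.114. Without control replicate 1, control replicate 2 or CLA replicate 1, 0 members fell, and without CLA replicate 3, 3 did. The mean was -2.60 and -1.32 within title numbers starting with 27 and 28.

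Skeletal muscle markers differed most of all between arrays and did not follow the fat lists on every array. All 21 tested members fell when adjusted over the list alone and 0 over all genes, with Myl1, Atp2a1, Ckm and Ttn, of the contractile apparatus and its energy supply, at log2 changes of -4.58, -3.77, -4.11 and -3.42. The mean was -3.50 (camera adjusted p = 6.14e-26; adjusted p = 0.165 with an estimated correlation), with an exact permutation p of 0.114. The score was 0.70, 3.95 and 1.36 on control replicates 1 to 3 and 1.18, -3.03, -1.31 and -2.84 on CLA replicates 1 to 4, so the groups overlapped. CLA replicate 1, within the control range for muscle, had a white adipocyte score of -0.80, and CLA replicate 4 one of 0.30. The difference was 0.48 within title numbers starting with 27 and -5.05 within those starting with 28, and without control replicate 2, 0 members fell. With the muscle score as a covariate, 5 synthesis, 12 white adipocyte, 5 oxidation and 0 brown adipocyte members fell when adjusted over the list alone, while the list means were -0.68, -1.47, -0.72 and -1.86 (camera adjusted p = 1.16e-14, 2.13e-28, 2.86e-22 and 6.06e-07). The brown adipocyte score coefficient went from -1.71 ± 0.67 (SE) to -1.86 ± 1.10.

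**Figure D3:**
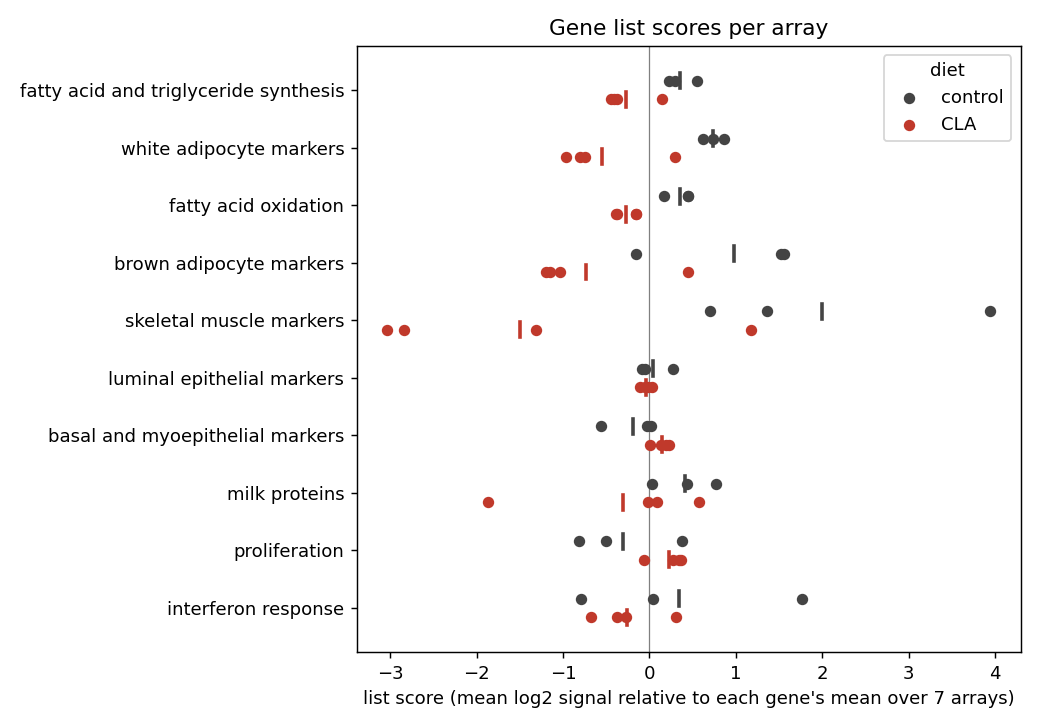
Score of 10 gene lists on each control array (grey, n = 3) and each CLA array (red, n = 4), the mean over members of log2 signal relative to each gene's mean over the 7 arrays, with vertical bars at group means. The white adipocyte score of CLA replicate 4 is 0.30 and those of the other CLA arrays lie between -0.96 and -0.75, and the muscle score ranges from -3.03 to 3.95.

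Luminal epithelial markers showed no shift past the test. Their mean log2 change was -0.08 (camera adjusted p = 0.314), 0 of 25 members passed over the list alone or over all genes, and the members of smallest p were the mucin gene Muc1 (-0.54), the keratin Krt7 (0.45), Ly6d (-1.15) and Cldn7 (0.15). With an array left out Ly6d ran from -1.73 to -0.25 and Muc1 from -0.80 to -0.31. Basal and myoepithelial markers had a mean of 0.33, and the basal keratins Krt17, Krt5 and Krt14 rose 3.17-fold, 2.36-fold and 2.65-fold when adjusted over the list alone, 3 of 17 members, with 0 over all genes. Cav1, also expressed in adipocytes and endothelium, had -0.66 and did not pass. The list's camera adjusted p = 0.0386 became adjusted p = 0.358 with an estimated correlation. Its call ended without control replicate 2 (mean 0.14, camera adjusted p = 0.450) and without CLA replicate 1, 2 or 4 (camera adjusted p = 0.0642, 0.0918 and 0.0517) and with the 60th percentile filter (mean 0.28, camera adjusted p = 0.179), and 0 members rose without control replicate 2, control replicate 3, CLA replicate 1 or CLA replicate 2. With the muscle score as a covariate the basal mean was 0.06 (camera adjusted p = 0.704). Cell junction genes had a mean of 0.15 (camera adjusted p = 0.255), or 0.06 with the muscle score as a covariate, with 0 of 31 past either adjustment, among them Dsp (1.09), Ppl (0.50), Cldn8 (0.39) and Lama5 (-0.52).

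Milk protein genes had a mean log2 change of -0.72 (camera adjusted p = 4.77e-06; adjusted p = 0.401 with an estimated correlation), and 0 of 15 members passed over the list alone or over all genes. Olah, which ends medium-chain fatty acid synthesis, had -1.70, the lipid droplet gene Plin2 -0.52, the casein gene Csn1s2b -1.52 and the lactoferrin gene Ltf -0.45. The score was -1.87 on CLA replicate 3, the array with the highest 3′ to 5′ ratio, and without that array the mean was -0.20 (camera adjusted p = 0.0719). With the 3′ to 5′ ratio as a covariate it was -0.51 (camera adjusted p = 3.27e-05). Within title numbers starting with 27 and 28 it was 0.06 and -1.04.

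Proliferation genes had higher signal in CLA glands in 32 of 32 tested members, with a mean log2 change of 0.54, but 0 passed over the list alone or over all genes. The camera adjusted p = 9.82e-15 with the preset correlation became adjusted p = 0.358 with an estimated correlation, and the exact permutation p of the score was 0.286. The replication helicase genes Mcm7 (0.62) and Mcm6 (0.75), the cyclin gene Ccne1 (1.01) and the ribonucleotide reductase gene Rrm2 (0.77) had the smallest p. The difference was -0.11 within title numbers starting with 27 and 0.87 within those starting with 28, 0.89 without control replicate 1 and 0.29 without control replicate 2. Control replicate 2 had the lowest proliferation score, -0.81, and the highest muscle score, and with the muscle score as a covariate the mean was 0.12 (camera adjusted p = 0.140).

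Fibroblast and extracellular matrix genes had a mean of 0.22 (camera adjusted p = 0.00119; adjusted p = 0.448 with an estimated correlation). None passed singly, 0 of 29 over the list alone or over all genes, with the matrix genes Tnc (0.59), Fn1 (0.56), Mmp14 (0.46) and Col1a2 (0.22) of smallest p, and the call ended without control replicate 1 (mean 0.15) or CLA replicate 3 (mean 0.12) and within title numbers starting with 28 (camera adjusted p = 0.132). With the muscle score as a covariate the fibroblast mean was 0.41 (camera adjusted p = 6.19e-10). Endothelial markers had a mean of -0.22 (camera adjusted p = 0.00106; adjusted p = 0.358 with an estimated correlation), with 0 of 18 past either adjustment and Flt1 (-0.58), Ptprb (-0.39), Esam (-0.31) and Cdh5 (-0.52) of smallest p. With an array left out Flt1 ran from -0.73 to -0.23, Ptprb from -0.51 to -0.23 and Cdh5 from -0.85 to -0.32. The list mean was 0.10 within title numbers starting with 27 and -0.38 within those starting with 28. It was -0.36 without control replicate 1, and the call ended without control replicate 2 (mean -0.11) and with the muscle score as a covariate (mean -0.01).

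Among immune lists, macrophage markers had a mean of 0.14 (camera adjusted p = 0.203). Cd163, a haptoglobin scavenger receptor, fell 2.09-fold when adjusted over the list alone, as 1 of 29 members, and 0 passed over all genes. Ccl8 (1.05), Cd14 (-0.68) and Gpnmb (1.61) did not pass, and without control replicate 2 the list mean was 0.31 (camera adjusted p = 5.36e-05). Without control replicate 3 it was 0.01 (camera adjusted p = 0.896), with Gpnmb at 0.60, and with the muscle score as a covariate 0.31 (camera adjusted p = 0.000115). Inflammatory and acute phase genes had a mean of -0.25 (camera adjusted p = 0.0256; adjusted p = 0.480 with an estimated correlation), and 2 of 18 fell when adjusted over the list alone, with 0 over all genes. These were the acute phase genes Orm1 (4.51-fold) and Hp, haptoglobin (2.61-fold), while Il1b (0.46) and Saa1 (-0.44) did not pass. The list's call ended without control replicate 2 (mean -0.07), CLA replicate 1 (mean -0.18) or CLA replicate 3 (mean -0.18), and the mean was -0.40 without control replicate 3 and -0.42 without CLA replicate 4. The call also ended as means of a gene's probe sets (mean -0.24), with the muscle score (mean -0.16) and with the 3′ to 5′ ratio (mean -0.25) as a covariate, while the 60th percentile filter gave a mean of -0.45 (camera adjusted p = 0.000662). Interferon response genes had a mean of -0.59 (camera adjusted p = 6.73e-06; adjusted p = 0.480 with an estimated correlation), with 0 of 21 past either adjustment. Iigp1 (-1.14), Bst2 (-0.92), Ddx58 (-0.35) and Gbp2 (-0.41) had the smallest p, but were -0.51, -0.09, -0.17 and -0.00340 without control replicate 2. Their score was 1.77 on control replicate 2, the mean turned to 0.12 without it and was -1.21 without control replicate 1, and the difference was 1.11 within title numbers starting with 27 and -1.35 within those starting with 28. With the muscle score as a covariate the interferon response mean was 0.78, past the test in the other direction (camera adjusted p = 6.19e-10). Lymphocyte markers had a mean of -0.06 and a median of 0.00, camera gave the direction up (adjusted p = 0.772), and 0 of 11 passed either adjustment, with Ighm (0.63), Cd22 (0.46), Il7r (0.70) and Ltb (-1.24) of smallest p. As means of a gene's probe sets the list had -0.53 (camera adjusted p = 0.0778).

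Cholesterol synthesis genes had a mean of 0.09 (camera adjusted p = 0.422), with 0 of 19 past either adjustment and Dhcr7 (0.28), Insig1 (-0.48), Sqle (0.28) and Lss (0.25) of smallest p. The list passed camera without control replicate 1 (mean 0.22) and without CLA replicate 3 (mean 0.26), and with the 3′ to 5′ ratio as a covariate (mean 0.17, camera adjusted p = 0.0104). Nerve and Schwann cell markers (mean -0.01, camera adjusted p = 0.688, 0 of 9 past either adjustment) were led by Pmp22 (-0.37), Mal (0.67), Scn7a (-0.37) and Gfra3 (-0.64). Immediate early and stress genes (mean -0.03, camera adjusted p = 0.505, 0 of 26) were led by Hspa1a (-0.58), Klf4 (-0.54), Btg2 (-0.47) and Atf3 (0.29). Skin markers had 3 members above the filter, Sbsn (-0.27), Krt10 (0.25) and Lor (-0.13), and blood markers 2, Hbb-b2 (-0.34) and Alas2 (0.13), too few for camera, and 0 of these passed over the list alone or over all genes.

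By camera with the preset correlation, 10 of the 20 lists tested were lower and 3 higher in CLA glands, and with an estimated correlation 0 passed. In simulated lists of 20 genes without an effect and with an inter-gene correlation of 0.5, the preset correlation called 53.5% and the estimated one 3%. The estimated correlation of the called lists ran from 0.04 for basal markers to 0.86 for interferon response. These simulated shares are therefore not the error rate of each list.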

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

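The tests of a swap with a control array and of RNA quality were chosen after the result was seen. The test of a wrong label on genes outside the lists was written before its result was seen.

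CLA replicate 4 stood apart from the other 3 CLA arrays in 3 list scores, its gap to the nearest array being a larger share of the group's range than Dixon's critical value for 4 arrays. Its score was 0.15 for fat synthesis, against -0.44 to -0.37 on the others, 0.30 for white adipocyte markers, against -0.96 to -0.75, and 0.45 for brown adipocyte markers, against -1.20 to -1.04. Chance alone flags about 1 in 20 groups, which for the 44 results examined this way is close to the number seen, and these 3 lists share adipocyte biology and are not independent.

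A swap with a control array is argued against, because the lowest mean score of the synthesis and adipocyte lists on a control array was 0.42, above the middle of -0.04 between the groups. RNA quality is argued against, because the mean log2 3′ to 5′ ratio of this array, 0.222, lay inside the range of the others, 0.0456 to 0.983. A single wrong label stays open and may account for the pattern. Over 12066 genes outside the lists, on an axis with the controls at 0 and the other CLA arrays at 1, this array lay at 0.229, and the other CLA arrays placed the same way at 0.471, 0.506 and 0.883. Noise of the control mean enters both the axis and each position, so an array without a diet effect need not lie at 0. With equal noise and no diet effect on any array, positions would lie about midway on average. The values of 0.471 and 0.506 are near that, so the position of 0.229 cannot decide about a wrong label. No control array was placed the same way. A gland that truly responded less to the diet would give the same values, and no value here decides between these explanations, although its Fasn signal of 8576 lay below every control array.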

How the results depend on the processing

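The muscle and RNA quality covariates were chosen after seeing the data; all other alternatives were fixed before. No paired analysis was possible because the labels give no replicate numbers shared between the diets. Fasn kept its direction under every alternative, from -1.39 to -1.13 with an array left out and from -1.30 to -1.12 otherwise, with limma adjusted p from 0.0227 to 1.00, and passed only without CLA replicate 4 (-1.36). With an array left out, genes called higher ran from 0 to 2 (2 without control replicate 1) and lower from 0 to 17 (17 without CLA replicate 4); array weights called 1 higher and 2 lower, and the arrays with title numbers starting with 28 called 1 higher and 0 lower. Genes at an unadjusted p under 0.05 ranged from 370 to 1377 with an array left out and from 295 with the muscle covariate to 1945 with array weights. Against 10 lists lower and 3 higher by camera, an estimated correlation gave 0 and 0, fry gave 1 and 0, and the muscle covariate gave 6 lower. The means of fat synthesis (-0.62), white adipocyte (-1.29) and oxidation (-0.62) no longer passed with an estimated correlation, which allows for members that vary together, nor the former pair with fry. Members that fell when adjusted over the list alone ranged from 7 to 18 for fat synthesis and from 4 to 16 for oxidation with an array left out. The mean of a gene's probe sets gave 11 white adipocyte and 10 oxidation members, the titles starting with 28 gave 11 synthesis, 8 white adipocyte and 2 oxidation members with fewer arrays, and the muscle covariate gave 5 synthesis and 5 oxidation members with means of -0.68 and -0.72 and larger standard errors. Signs turned, the cause not tested, for the nerve list under quantile normalization (0.0093), pseudocounts of 16 (0.00420) and 64 (0.020), no filter (0.031), the 60th percentile filter (0.081) and titles starting with 28 (0.069, with Gfra3 at 0.023). The mean of probe sets turned Timp2 (-0.22), Cycs (0.14) and Ndufb9 (0.27). The muscle covariate turned Ndufb9 (0.084), Ltb (0.44), Iigp1 (0.25), Bst2 (0.39), Ddx58 (0.17), Gbp2 (0.22), Lor (0.42) and the cholesterol (-0.087), lymphocyte (0.34), interferon (0.78) and immediate early (0.046) lists, of which only interferon passed, as higher (camera adjusted p = 6.19e-10). With an array left out the sign turned within these ranges: Krt10 -0.16 to 0.47, Lor -0.31 to 0.39, Alas2 -0.32 to 0.44, cholesterol -0.0104 to 0.26, luminal -0.15 to 0.035, lymphocyte -0.24 to 0.024, interferon -1.21 to 0.12, nerve -0.13 to 0.14 and immediate early -0.10 to 0.076. Each gene or list was counted once per alternative. For named genes other than Fasn, 2062 such values kept their direction and side of the threshold, 13 came to pass it and 15 changed sign. For list means, 346 values kept both, 49 lost their call, 5 came to pass and 18 changed sign. These sign changes are the ones given above. With an array left out, 42 of the 96 named genes other than Fasn had a log2 change over 1.5 times as large or as small. The filter leaves genes with signal near background untested.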

Other observations

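The tests of muscle tissue, of muscle carry-over, of RNA quality, of fewer adipocytes and of other splits for the number of genes past the threshold and for the adipocyte and oxidation lists without synthesis were chosen after the results were seen. The other splits and the tests of the keratin, macrophage and Vars hypotheses were written before their results were seen, although these hypotheses came from the same data.

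The exact permutation test of the fat list scores could not pass. It doubles the one-sided share, so with 3 against 4 arrays 0.0571 is the smallest p it can give. The number of fat list members past the test was highest in the real split. Of 68 members of the synthesis, white adipocyte and oxidation lists, 52 passed in either direction when adjusted over the list alone. These were 51 lower and 1, Fads2, higher. Of the 35 splits of the 7 arrays into 3 and 4, 1, the real one, gave as many. This share is the smallest that 35 splits allow, and it was not adjusted over the counts compared this way. Chance is therefore less likely for this number but not excluded. The highest other split gave 40 and set CLA replicates 1 to 3 against the rest. Without the synthesis list, to which the title had pointed, 34 members passed, 1 of the 35 splits gave as many and the highest other split gave 23. Chance cannot be excluded for the 13 lists past camera, since 2 of the 35 splits gave as many and the highest other split also gave 13. For the 0 genes past the adjusted limma threshold the splits decide nothing, since any count matches 0 and all 35 did, with 11 in the highest other split, again CLA replicates 1 to 3 against the rest. Chance cannot be excluded for the 674 genes at an unadjusted p under 0.05, which 14 splits matched. The highest other split there gave 2106 genes and set control replicates 2 and 3 with CLA replicate 3 against the rest, which points to a structure of the samples apart from diet. That split kept both arrays with title numbers starting with 27 on one side and set the 3 arrays with the highest mean log2 3′ to 5′ ratio, 0.434, 0.274 and 0.983, against 0.0456 to 0.222 on the rest, so RNA quality stays open beside the title number. With the title number as a block the count was 935, within the titles starting with 28 it was 1229, and with the 3′ to 5′ ratio as a covariate it was 925.

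The diet coefficients of the fat transcripts stayed below 0 when other measured differences were allowed for. With the muscle score as a covariate the diet coefficient of the mean synthesis and adipocyte score went from -0.96 ± 0.26 (SE) to -1.07 ± 0.43. That of the oxidation score went from -0.62 ± 0.11 to -0.72 ± 0.17. With 4 residual degrees of freedom the synthesis and adipocyte coefficient is too imprecise to decide about muscle carry-over. The oxidation coefficient argues against muscle carry-over as the whole cause of the lower oxidation transcripts. Members lost their calls in that fit, where the standard errors grew in all 68. The coefficient grew in size in 15 of 25 synthesis, 16 of 20 white adipocyte and 17 of 23 oxidation members, and not in the others. In the synthesis, white adipocyte and oxidation lists the median SE went from 0.18, 0.34 and 0.18 to 0.28, 0.49 and 0.28, and the median log2 change from -0.68, -1.35 and -0.52 to -0.63, -1.50 and -0.55. With the 3′ to 5′ ratio as a covariate the coefficient was -0.94 ± 0.29, which argues against RNA quality. Fewer adipocytes in the CLA glands stay open and may be the cause, alone or with a response of the genes to the diet. The shifts of 5 other cell type lists had both signs. They were 0.33 for basal, 0.22 for fibroblast, 0.14 for macrophage, -0.08 for luminal and -0.22 for endothelial markers. Their range was 0.55 on the log2 scale. Of the 35 splits, 2 gave a range as large, the real one among them, with 0.60 in the highest other split. A range that other splits match cannot decide about adipocyte number.

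Skeletal muscle transcripts moved as a block. The mean pairwise correlation of the members' deviations from their group means was 0.838, above 100% of 10000 random lists, whose highest was 0.253, and the score spanned 6.98 log2 units over the 7 arrays. Acta1 signal ran from 31.8 to 19588. Interferon response (0.864) and proliferation (0.851) members were as strongly correlated, so moving together is not particular to muscle, and varying amounts of muscle tissue taken with the gland stay an open possibility. Whether the lower mean in CLA glands follows diet or dissection was not decided by any value here, and the proliferation score, 0.54 ± 0.32 (SE) without and 0.12 ± 0.45 with the muscle score as a covariate, depends on it.

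A hypothesis drawn from Krt5, Krt14 and Krt17 is a wider stratified epithelium programme in CLA glands. A separate list of 17 such genes had 16 on the array and 9 above the filter. The mean log2 change was 0.44, with 8 of the 9 tested members higher. Lgals7 was the only one that rose when adjusted over the list alone. The list was not examined with an array left out or with the muscle score as a covariate. Camera gave p = 0.00464 with the preset and p = 0.0322 with an estimated correlation, but after adjustment over the 4 hypothesis lists the latter was 0.129, and the exact permutation p of the score was 0.0571. These values are consistent with the hypothesis and may also reflect skin near the gland, whose own markers Sbsn, Krt10 and Lor had -0.27, 0.25 and -0.13.

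The macrophage genes Gpnmb and Cd163 prompted a hypothesis of lipid-laden in place of resident macrophages. A separate list of lipid-laden macrophage genes had a mean of 0.0215, with a median of -0.04, 7 of 12 members lower and the camera direction down (camera p = 0.389), and one of resident macrophage genes had -0.15 (camera p = 0.0490 and, with an estimated correlation, p = 0.302), so neither was decided. For Vars, a list of amino acid and endoplasmic reticulum stress genes had a mean of 0.10 (camera p = 0.0519 and, with an estimated correlation, p = 0.480), which leaves that hypothesis open too.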
